A study of Saccharomyces cerevisiae with 93 samples.

How the data were processed

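RNA of budding yeast was measured on 93 dual-colour arrays, each of which set 1 RNA sample in Cy5 against another in Cy3. Per the labels, alpha-synuclein was induced with galactose for 0, 2, 4 or 6 h, hot phenol was used to extract RNA, and a comparison rests on 3 pairs of biological replicates. Whether arrays of different comparisons shared a culture is not given in the sources used here. All arrays of a comparison had the same dye orientation, with no dye swap.

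The deposited values are log2 ratios, 1 per probe and array, normalised by the authors. The labels name limma as the tool; its version, background correction and normalisation are not given in the sources used here. Scale and direction are not stated either: the values were read as log2 of Cy5 over Cy3 from limma's convention, the order of the labels and the values themselves. They were signed, had array medians between -0.0306 and 0.0214, and had SDs between 0.126 and 0.731 per array. Raw intensities and slide identities were not analysed here, so that signal over background is unknown.

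Of 6377 probes, 5644 were named by their locus tag and 196 after the hyphen of the tag was written, while 537 matched no gene of the reference. All were tested, 5227 of them under a gene symbol, and 0 values were missing. No probe measured alpha-synuclein or its fluorescent tag. The label of 1 sample describes a W303 strain without the drug pump regulators PDR1 and PDR3 and with alpha-synuclein under a galactose promoter.

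Arrays were grouped by their labels into 30 groups of 3, apart from 2-copy over vector at 4 h with 6. A linear model with 1 mean per group was fitted to all 93 arrays with limma 3.58.1 in R 4.3.3, and moderated tests (two-sided) used 67.6 degrees of freedom, of which the prior gave 4.56. Adjusted p is the Benjamini-Hochberg value over all probes of a comparison, with a threshold of 0.05. Group means were tested against 0, and changes from 0 h, responses in 2-copy minus vector cells and pairs of compounds as differences of group means. Differences among the 6 compounds were tested with a moderated F. Values are mean log2 ratio ± SD over arrays, with SE where a difference is given.

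Gene lists, 29 in number, covered protein folding and degradation, secretion, mitochondria, ribosomes, metals, nutrients, lipids, stress, cell wall, cell cycle, mating and strain markers. They were written from textbook knowledge of yeast and tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Members past the threshold were counted over all probes and adjusted over the list alone.

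By rule, genes named in the text had a symbol and were past the threshold without and with a dye term. They had 1 sign on every array (for a difference, groups that did not overlap). By size of the mean, up to 12 highest and 12 lowest were taken for 2-copy over vector at 4 h and up to 5 and 5 at the other times and for each compound in 2-copy cells. Up to 3 and 3 were taken for every other comparison, with the 5 of smallest p in each F test. Besides these, up to 4 members of a described list were named, and 8 fixed genes of galactose use and drug efflux. The dye term was 1 further coefficient per gene in a model of strain and compound differences, and 4 probes had a dye effect past the threshold.

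An alpha-synuclein score was built from genes past the threshold in 2-copy over vector arrays 1 to 3 at 4 h. The score of an array was the mean of the genes that were higher minus the mean of those that were lower, divided by 2. Untreated arrays 4 to 6, which did not choose the genes, were compared with arrays of 2-copy over vector with compound by exact permutation (two-sided), and the 6 compounds with each other by a permutation test.

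The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a dye term, scaling of each array by its median absolute deviation, array weights, a fit to the arrays of a comparison alone, a block for replicate number and leaving out each replicate number. For differences between strains with compound, the other 2 sides of each loop of arrays were a further alternative. Residuals of same-numbered arrays in the 2 groups of a difference were correlated across genes above 0.1 for all 3 numbers in 1 of 9 differences, that of compound 6 (0.137, 0.174 and 0.193), so the block for replicate number was kept as an alternative. The 10 arrays described in the results were left out as an alternative chosen after seeing the data.

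The model was tested on simulated independent normal noise with each gene's spread, equal on all arrays. Known changes of 3 sizes were each added to 64 to 67 genes per comparison. For 2-copy over vector at 4 h, 77.6% of changes of 0.5 and 100% of changes of 1 were recovered, with 11 false calls. For compound 1 in 2-copy cells, 55.2% and 92.5% were recovered, with 7 false calls, and for a difference in response 30.8% and 82.1%, with 18. With a simulated dye effect of 1 on 200 genes, 200 were called without the dye term and 0 with it. Of 29 simulated lists, the 1 list shifted by 0.3 was called (camera adjusted p = 5.91e-29) and 0 others. The simulation could not test list calls where genes vary together or gene calls where arrays differ in spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.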

Results

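The series followed a yeast model of Parkinson's disease in which human alpha-synuclein is made from a galactose promoter, in strains with 1 or 2 copies of its gene or an empty vector. A time course at 0, 2, 4 and 6 h of induction set 2-copy against vector, 1-copy against vector and 1-copy against 2-copy cells. At 4 h, each of 6 related compounds was set against no compound in 2-copy cells and in vector cells, and 2-copy against vector cells were compared with the compound in both. The title names rescue from alpha-synuclein toxicity as the question. Every array gave a log2 ratio for 6377 probes. Genes named by rule had 1 sign on every array of a comparison. Of 321 gene list calls against 0, 281 had a list mean of 1 sign on every array.

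On 10 of the 93 arrays the genes with large ratios were not those that varied elsewhere. They were numbers 2 and 3 of 2-copy over vector with compounds 3, 4 and 6, numbers 2 and 3 of compound 3 in 2-copy cells, and number 3 of compounds 4 and 6 in 2-copy cells. Across genes, the size of their ratios correlated at 0.201 to 0.728 with the first 6 of these and at 0.0287 to 0.0757 with the scatter of genes in the time course. The other 83 arrays gave -0.00239 to 0.137 and 0.0224 to 0.368. Values without these 10 arrays, chosen after seeing the data, stand beside most results that used them, as values "on the kept arrays"; others use all arrays. Where 1 array was kept, it was assumed to vary like the other groups, so that its p has no replicate of its own.

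**Figure D1:**
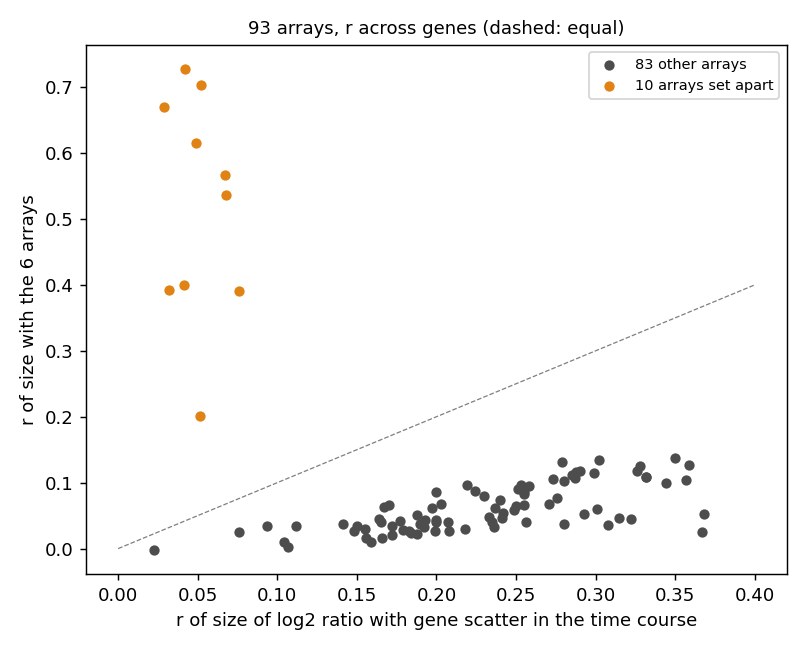
Each point is 1 of 93 arrays. The x axis is the correlation r across genes of the size of its log2 ratios with gene scatter in the time course and the y axis that with the 6 arrays of compounds 3, 4 and 6. The 10 arrays set apart lie above the dashed line of equality, at 0.201 or more on the y axis.

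The comparison of 2-copy with vector cells asked what alpha-synuclein does to gene expression. After 4 h (n = 6 arrays), the small heat shock protein HSP26 (YBR072W) was higher in 2-copy cells by 5.51 ± 0.515 and ULI1 (YFR026C), a gene induced by the unfolded protein response, by 5.43 ± 0.297. The cell wall protein PIR3 (YKL163W) was higher by 4.54 ± 0.241, the phosphate transporter PHO84 (YML123C) by 4.12 ± 0.7 and the ER chaperone KAR2 (YJL034W) by 3.57 ± 0.206. Arrays 1 to 3 and 4 to 6 did not overlap for HSP26 (5.74 to 6.06 against 4.74 to 5.28) or PHO84 (3.28 to 3.94 against 4.28 to 5.06). For ULI1, PIR3 and KAR2 the 2 sets overlapped. The other highest genes were HSP12 (YFL014W, 4.08), ROQ1 (YJL144W, 3.55), NCW2 (YLR194C, 3.51), YET2 (YMR040W, 3.50), the sulfate transporter SUL1 (YBR294W, 3.45), GND2 (YGR256W, 3.36) and THI12 (YNL332W, 3.33). The lowest were the hexose transporters HXT6 (YDR343C, -2.11 ± 0.549) and HXT7 (YDR342C, -2.02), cytochrome c CYC1 (YJR048W, -2.08 ± 0.448), the pyruvate carrier MPC3 (YGR243W, -2.07), the lactate transporter JEN1 (YKL217W, -2.00) and the endonuclease HO (YDL227C, -1.96). RPM2 (YML091C, -1.93), FUR4 (YBR021W, -1.89), PDH1 (YPR002W, -1.89), AIM33 (YML087C, -1.85), the copper chaperone COX17 (YLL009C, -1.82) and PUT4 (YOR348C, -1.71) completed them.

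Cytosolic and ER folding genes were higher as groups at 4 h. Mitochondrial chaperones were lower (mean -0.45, adjusted p = 0.139 with an estimated correlation). Of 24 cytosolic heat shock genes 20 were higher and 0 lower (21 and 0 adjusted over the list alone; list mean 1.17, camera adjusted p = 4.9e-08, adjusted p = 0.108 with an estimated correlation). BTN2 (YGR142W, 2.55), HSP42 (YDR171W, 2.46) and SSE2 (YBR169C, 2.37) came after HSP26. Of 20 ER chaperone and unfolded protein response genes 18 were higher and 0 lower (18 and 0 adjusted over the list alone; mean 1.23, adjusted p = 1.43e-08, adjusted p = 0.098 with an estimated correlation). Among them were the oxidase ERO1 (YML130C, 2.97), SIL1 (YOL031C, 2.39) and the disulfide isomerase PDI1 (YCL043C, 1.89). ER to Golgi transport genes were higher in 26 and lower in 5 of 42 (27 and 5 adjusted over the list alone; mean 0.29, adjusted p = 0.00123, adjusted p = 0.098 with an estimated correlation). The proteasome list was higher in 32 of 37 (33 adjusted over the list alone; mean 0.46, adjusted p = 2.98e-05, adjusted p = 0.246 with an estimated correlation). Cell wall integrity genes were higher in 17 and lower in 1 of 22 (mean 1.30, adjusted p = 1.16e-06, adjusted p = 0.0985 with an estimated correlation). PST1 (YDR055W) stood at 3.12 and the wall protease YPS1 (YLR120C) at 2.65.

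Mitochondrial and ribosomal genes were lower. Respiratory chain and ATP synthase genes were lower in 31 and higher in 1 of 37 (32 and 1 adjusted over the list alone; mean -0.70, adjusted p = 3.5e-12, adjusted p = 0.0433 with an estimated correlation). RIP1 (YEL024W) stood at -1.32 and ATP14 (YLR295C) at -1.27. Of 71 mitochondrial ribosome genes 70 were lower and 1 higher (mean -0.92, adjusted p = 1.13e-23, adjusted p = 0.108 with an estimated correlation). MRP1 (YDR347W) stood at -1.56. TCA cycle genes were lower in 15 and higher in 1 of 17 (mean -0.77, adjusted p = 5.23e-06, adjusted p = 0.098 with an estimated correlation). Aconitase ACO1 (YLR304C) stood at -1.66 ± 0.58. Cytosolic ribosomal protein genes were lower in 98 of 111 (mean -0.62, adjusted p = 1.47e-18, adjusted p = 0.133 with an estimated correlation). In all, 2002 genes were higher and 1838 lower after limma's adjustment (1476 and 1466 with a dye term). Among fixed genes, GAL1 (YBR020W), which shares the galactose regulation of the construct, stood at -0.44 ± 0.269 (adjusted p = 4.03e-05, n = 6). GAL10 (YBR019C) stood at -0.35 and GAL7 (YBR018C) at 0.21. The efflux pump PDR5 (YOR153W) was higher by 1.45 ± 0.184, with SNQ2 (YDR011W) at 0.49 and YOR1 (YGR281W) at 0.45.

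At 0 h (n = 3), 2-copy cells already differed from vector cells. The copper transporter CTR1 (YPR124W) was higher by 2.15 ± 1.29 (adjusted p = 3.5e-07) and COX17 by 1.44 ± 1.05, with MAM33 (YIL070C, 1.38), MDM35 (YKL053C-A, 1.21) and MRPL31 (YKL138C, 1.21). FAT3 (YKL187C, -1.47 ± 0.646), carnitine acetyltransferase CAT2 (YML042W, -1.44), UTR1 (YJR049C, -1.39), acetyl-CoA synthetase ACS1 (YAL054C, -1.28) and the hypoxic repressor ROX1 (YPR065W, -1.28) were lowest. Mitochondrial ribosome genes were higher in 52 of 71 (62 adjusted over the list alone; mean 0.69, adjusted p = 4.72e-36, adjusted p = 0.184 with an estimated correlation). Ergosterol genes were lower in 9 of 26 (17 lower and 1 higher adjusted over the list alone; mean -0.38, adjusted p = 1.02e-07, adjusted p = 0.214 with an estimated correlation). The lanosterol demethylase gene ERG11 (YHR007C) stood at -0.90. In total 466 genes were higher and 354 lower (199 and 129 with a dye term). Without replicate 3 the total of 820 became 301, and in a fit to the 3 arrays alone it was 0.

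At 2 h (n = 3), PHO84 was higher by 2.68 ± 0.289, ULI1 by 2.29 ± 0.165, inositol phosphate synthase INO1 (YJL153C) by 2.28 ± 0.271, KAR2 by 2.02 ± 0.632 and ERO1 by 1.96 ± 0.288. The aromatic aminotransferase ARO9 (YHR137W, -2.40 ± 0.673), URA3 (YEL021W, -1.69), AIM44 (YPL158C, -1.34), HO (-1.28) and the daughter-cell glucanase SCW11 (YGL028C, -1.22) were lowest. ER chaperone genes were higher in 10 of 20 (11 adjusted over the list alone; mean 0.65, adjusted p = 2.26e-08, adjusted p = 0.083 with an estimated correlation). Cell wall genes were higher in 11 of 22 (12 higher and 1 lower adjusted over the list alone; mean 0.63, adjusted p = 1.89e-07, adjusted p = 0.087 with an estimated correlation). PIR3 stood at 1.74. Totals were 363 higher and 273 lower (254 and 154 with a dye term). Without replicate 3 the total of 636 became 165.

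At 6 h (n = 3), ULI1 (5.23 ± 0.553), KAR2 (3.65 ± 0.219), proline oxidase PUT1 (YLR142W, 3.57 ± 0.17), NCW2 (3.36) and carbonic anhydrase NCE103 (YNL036W, 3.12) were highest. The pheromone gene MF(ALPHA)2 (YGL089C, -3.14 ± 0.697), IMD2 (YHR216W, -2.46), AAD4 (YDL243C, -2.33), HXT3 (YDR345C, -2.29) and glutathione transferase GTT2 (YLL060C, -2.26) were lowest. ER to Golgi genes were higher in 23 and lower in 1 of 42 (mean 0.32, adjusted p = 6e-05, adjusted p = 0.0137 with an estimated correlation). ER chaperone genes were higher in 15 and lower in 1 of 20 (mean 0.99, adjusted p = 5.42e-06, adjusted p = 0.129 with an estimated correlation). Oxidative stress genes were lower in 18 and higher in 0 of 30 (mean -0.84, adjusted p = 4.99e-10, adjusted p = 0.0137 with an estimated correlation). OYE3 (YPL171C) stood at -2.10. At 4 h 18 of this list had been higher and 2 lower (mean 0.57, adjusted p = 0.000326, adjusted p = 0.133 with an estimated correlation). Amino acid biosynthesis genes were lower in 31 of 55 (33 adjusted over the list alone; mean -0.43, adjusted p = 2.52e-07, adjusted p = 0.0657 with an estimated correlation). Cytosolic ribosomal proteins, lower at 4 h, were higher in 66 and lower in 3 of 111 (70 and 3 adjusted over the list alone; mean 0.47, adjusted p = 3.78e-09, adjusted p = 0.438 with an estimated correlation). Totals were 1383 higher and 1211 lower (1140 and 1167 with a dye term).

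**Figure D2:**
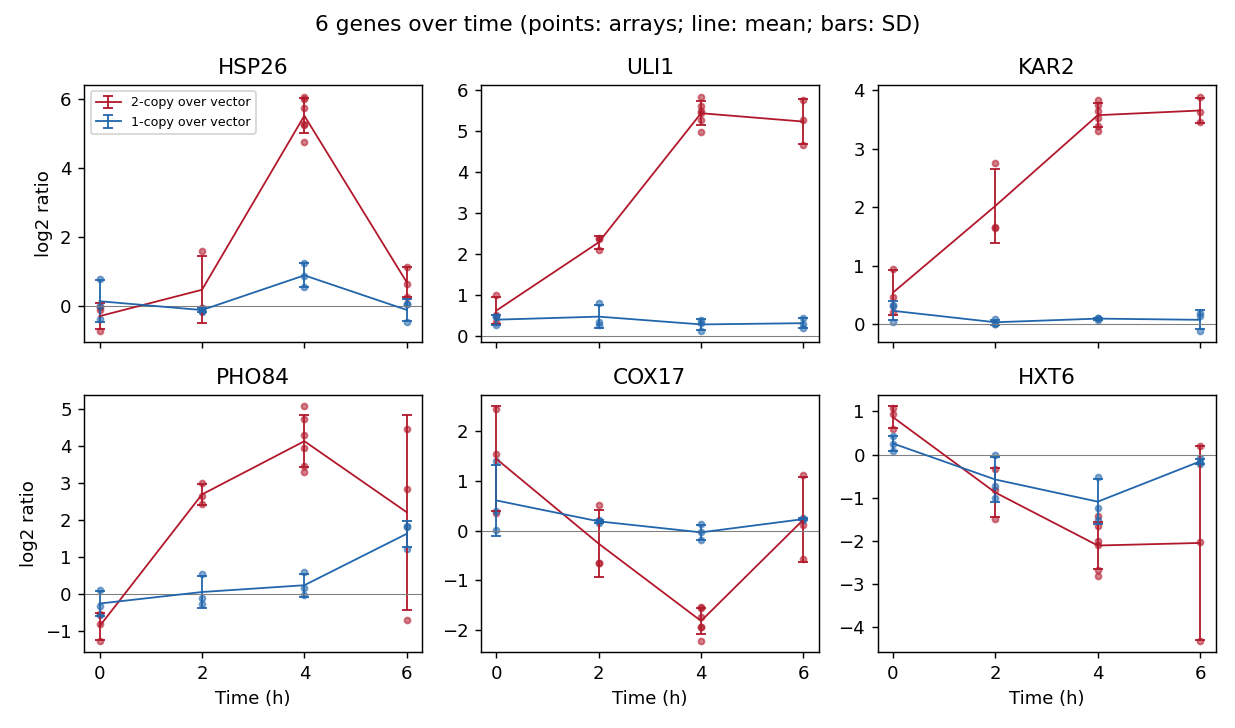
Log2 ratios (y axis) of 6 genes against hours of induction (x axis) in 2-copy and 1-copy cells over vector; points are arrays, lines means and bars SD. At 4 h, HSP26, ULI1, KAR2 and PHO84 stood at 5.51, 5.43, 3.57 and 4.12 in 2-copy cells, and COX17 and HXT6 at -1.82 and -2.11.

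One-copy cells, which asked how far the response needs the second copy, had fewer genes that differed from vector cells than 2-copy cells had at each time, except at 0 h with array weights (1789 against 438) and in fits to their own arrays. URA3, the uracil marker enzyme, was lower at 0, 2, 4 and 6 h (-1.17, -1.56, -2.26 ± 0.109 and -2.21 ± 0.459; n = 3 each). UTR1 was lower at 0 h (-2.22 ± 0.0236) and at 4 h (-1.88 ± 0.13) and YAP3 (YHL009C) at 0 h (-0.93). Formate dehydrogenase FDH1 (YOR388C) was higher at 6 h (1.58 ± 0.173). Mating type alpha genes at 4 h were lower in 1 of 4 (2 adjusted over the list alone; mean -0.62, adjusted p = 0.000391, adjusted p = 0.0468 with an estimated correlation). Pheromone response genes were lower in 1 of 13 (4 adjusted over the list alone; mean -0.19, adjusted p = 0.00277, adjusted p = 0.0493 with an estimated correlation). HSP26 stood at 0.89 at 4 h (adjusted p = 0.66). Totals at the 4 times were 162, 304, 36 and 52 genes, of which 39, 37, 5 and 8 were higher. They were 501, 683, 634 and 728 with array scaling and 1789, 1177, 1339 and 671 with array weights. With a dye term 3, 1, 2 and 4 genes were past the threshold: the genes just named, with YAR073W (-1.48) and YPL277C (0.72) at 6 h, chosen after their values were seen. Without 1 replicate the totals fell to as few as 30 (without 2), 53 (without 3), 4 (without 3) and 11 (without 2).

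Set directly against 2-copy cells, 1-copy cells had lower ULI1 (-5.00 ± 0.326), HSP26 (-4.71 ± 0.882) and PIR3 (-3.89 ± 0.567) at 4 h and higher HO (2.24 ± 0.14), the ADP/ATP carrier PET9 (YBL030C, 2.17) and MPC3 (2.13). ER chaperone genes were lower in 13 of 20 at 2 h (15 adjusted over the list alone; mean -0.75, adjusted p = 5e-12, adjusted p = 0.0532 with an estimated correlation). At 4 h they were lower in 17 (mean -1.22, adjusted p = 5.17e-09, adjusted p = 0.113 with an estimated correlation). At 6 h they were lower in 14 and higher in 1 (mean -0.92, adjusted p = 1.2e-06, adjusted p = 0.143 with an estimated correlation). Mitochondrial ribosome genes were higher in 69 and lower in 1 of 71 at 4 h (mean 0.99, adjusted p = 3.09e-25, adjusted p = 0.113 with an estimated correlation). Oxidative stress genes were higher in 21 of 30 at 6 h (mean 0.85, adjusted p = 4.93e-11, adjusted p = 0.0142 with an estimated correlation). At 0 h FAT3 (1.06), FBP1 (YLR377C, 0.94) and SSA3 (YBL075C, 0.92) were higher and CTR1 (-1.25), TRP1 (YDR007W, -1.12) and FRE7 (YOL152W, -0.80) lower. At 2 h HO (1.52), AMN1 (YBR158W, 1.24) and AIM44 (1.19) were higher and PHO84 (-2.69 ± 0.128), KAR2 (-2.05) and GIT1 (YCR098C, -2.04) lower. At 6 h FDH1 (2.90 ± 0.39), MF(ALPHA)1 (YPL187W, 2.35) and the zinc transporter ZRT1 (YGL255W, 2.34) were higher and ULI1 (-4.65), PUT1 (-3.41) and KAR2 (-2.95) lower. Totals were 223, 622, 2925 and 2377 genes (24, 204, 2977 and 2091 with a dye term). Without replicate 3 the first and second became 15 and 234, and in a fit to its 3 arrays alone the first was 0.

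Changes of the 2-copy over vector ratio from 0 h, in which a fixed dye effect and a strain difference cancel, were tested at each later time. By 2 h the ratio of PHO84 had risen by 3.56 (2.68 against -0.88), of INO1 by 2.45 and of SIP18 (YMR175W) by 2.02. CTR1 had changed by -2.37, hexokinase HXK1 (YFR053C) by -2.23 and MAM33 by -1.91. By 4 h HSP26 had risen by 5.80 (SE 0.623), PHO84 by 5.00 and ULI1 by 4.80, and COX17 (-3.26), MAM33 (-3.09) and HXT6 (-2.98) had fallen. By 6 h ULI1 (4.60), PUT1 (3.74) and NCW2 (3.53) had risen and MF(ALPHA)2 (-3.03), HXT6 (-2.92) and MF(ALPHA)1 (-2.71) had fallen. Mitochondrial ribosome genes fell in 46 of 71 by 2 h (60 adjusted over the list alone; mean -0.90, adjusted p = 1.58e-51, adjusted p = 0.0211 with an estimated correlation). By 4 h they fell in 70 and rose in 1 (mean -1.61, adjusted p = 1e-46, adjusted p = 0.029 with an estimated correlation). ER chaperone genes rose in 14 of 20 by 4 h (mean 1.07, adjusted p = 5.74e-06, adjusted p = 0.138 with an estimated correlation). The genes past the threshold numbered 300 at 2 h (91 up, 209 down), 2443 at 4 h (1322 up, 1121 down) and 1482 at 6 h (757 up, 725 down). Without replicate 3 the first and last became 60 and 864, and in a fit to their own arrays 11 and 454.

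The compounds share a ring system of a lactam fused to an aromatic ring. In compounds 1, 2 and 6 that aromatic part is a benzo-fused quinolinone, which carries a 3-iodophenyl group in 1, a 3-bromophenyl group in 2, and in 6 a 4-ethylphenyl group with a bromine on the rings and 1 stated stereocentre. In compounds 3, 4 and 5 it is a dimethyl quinolinone, with a bromofluorophenyl group in 3 and 4, which differ in where bromine and fluorine sit, and a substituent that the labels write as 4-ethyl in 5. All arrays were taken at 4 h, and the doses are not given in the labels.

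In 2-copy cells (n = 3 arrays per compound), compounds 1 and 2 raised siderophore iron uptake genes. The cell wall mannoproteins FIT2 (YOR382W) and FIT3 (YOR383C), which retain siderophore iron, rose by 4.27 ± 0.448 and 3.51 ± 0.329 with compound 1 and by 4.37 ± 0.0363 and 3.51 ± 0.334 with compound 2. The mating fusion gene PRM1 (YNL279W) rose by 2.91 and 2.87 and CSS1 (YIL169C) by 2.26 and 2.34. HPF1 (YOL155C) rose by 2.04 with compound 1 and the glucose transporter HXT4 (YHR092C) by 2.17 with compound 2. ULI1 fell by 3.35 and 4.17, KAR2 by 3.16 and 3.74, HSP26 by 2.75 and 3.09 and the serine hydroxymethyltransferase SHM2 (YLR058C) by 2.72 and 3.15. SNZ1 (YMR096W) stood at -2.92 with compound 1 and ERO1 at -3.14 with compound 2.

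As groups, iron regulon genes rose in 17 and fell in 0 of 27 with each of these compounds. Adjusted over the list alone 18 rose with compound 1 (mean 1.01, adjusted p = 1.94e-09, adjusted p = 0.143 with an estimated correlation). For compound 2 that number was 17 (mean 1.01, adjusted p = 2.23e-09, adjusted p = 0.135 with an estimated correlation). The siderophore transporter ARN1 (YHL040C) stood at 1.99 and 2.02 and the iron oxidase FET3 (YMR058W) at 1.59 and 1.68. ER chaperone genes fell in 15 of 20 with compound 1 (18 adjusted over the list alone; mean -1.12, adjusted p = 1.77e-11, adjusted p = 0.0756 with an estimated correlation). With compound 2 they fell in 16 (17 adjusted over the list alone; mean -1.26, adjusted p = 2.61e-12, adjusted p = 0.0237 with an estimated correlation). Heat shock genes fell in 17 of 24 with each (21 and 19 adjusted over the list alone; means -0.83 and -0.88, adjusted p = 1.25e-07 and 6.73e-08, adjusted p = 0.143 and 0.135 with an estimated correlation). Mitochondrial ribosome genes rose in 51 and 42 of 71 and fell in 1 and 1 (means 0.57 and 0.45, adjusted p = 8.52e-15 and 2.97e-10, adjusted p = 0.247 and 0.241 with an estimated correlation). Cell wall genes fell in 13 and 14 of 22 (means -0.91 and -0.93, adjusted p = 1.57e-06 and 2.36e-06, adjusted p = 0.143 and 0.135 with an estimated correlation). Compound 1 changed 977 genes up and 1174 down (529 and 953 with a dye term), and compound 2 changed 966 up and 1229 down (591 and 1012). Both totals were lower by a factor of over 1.5 with array scaling and in fits to their own arrays.

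**Figure D3:**
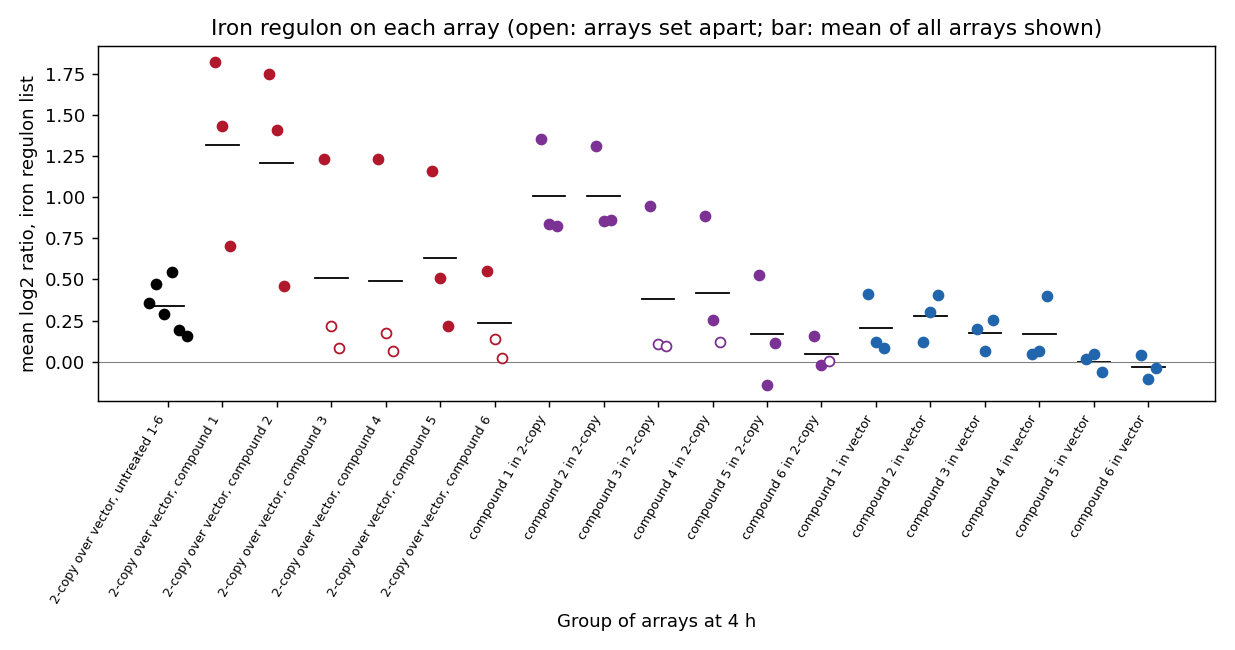
Mean log2 ratio of the 27 iron regulon genes (y axis) on each array by group at 4 h (x axis); points are arrays, open for the 10 set apart, and bars are means of all arrays shown. With compounds 1 and 2 in 2-copy cells the 6 arrays lay between 0.827 and 1.35, and in vector cells between 0.0857 and 0.410.

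Compounds 3 and 4 lowered phosphate genes in 2-copy cells (n = 3 each), as compounds 1 and 2 did (with these PHO84 stood at -2.29 and -2.57, SPL2 at -2.05 and -2.45, PHO89 at -1.64 and -2.06 and HXT2 at -1.50 and -1.94). The phosphate transporter PHO89 (YBR296C) fell by 2.33 ± 0.4 and 2.22 ± 0.281, the phosphate regulator SPL2 (YHR136C) by 2.28 ± 0.304 and 2.31 ± 0.167 and PHO84 by 2.04 and 2.14. YET2 (-1.91 and -1.49) and the glucose transporter HXT2 (YMR011W, -1.82 and -1.93) fell too. The cell wall protein CWP1 (YKL096W, 1.39 and 1.24) and the daughter-cell glucanase DSE4 (YNR067C, 1.28 and 1.34) rose with both. With compound 3 SCW11 (1.15), GAC1 (YOR178C, 1.14) and chitinase CTS1 (YLR286C, 1.10) rose, and with compound 4 CSS1 (1.69), HPF1 (1.59) and FIT3 (1.49 ± 1.5). On the kept arrays, 1 for compound 3 and 2 for compound 4, PHO89 stood at -2.32 and SPL2 at -2.50 with compound 3 and at -2.07 and -2.30 with compound 4. Kept values for compounds 3 and 4 were -2.03 and -1.47 for YET2, -1.41 and -1.90 for HXT2, 1.67 and 1.40 for CWP1 and 1.49 and 1.42 for DSE4. With compound 3 they were 1.65 for SCW11 and 1.23 for CTS1, and with compound 4 2.47 for CSS1, 2.34 for HPF1, 2.18 for FIT3 and -2.12 for PHO84. On the 1 kept array of compound 3, a number 1 array, GAC1 stood at 0.65, PHO84 at -1.67, FIT2 at 3.42 and KAR2 at -2.19. That array has no replicate, so that its values carry no spread of their own.

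Phosphate regulon genes fell in 10 and 12 of 17 and rose in 3 and 3 with compounds 1 and 2 (means -0.60 and -0.75, adjusted p = 0.0073 and 0.00129, adjusted p = 0.278 and 0.238 with an estimated correlation). They fell in 5 of 17 with compound 3 (5 fallen and 1 risen adjusted over the list alone; mean -0.58, adjusted p = 0.000415, adjusted p = 0.388 with an estimated correlation). With compound 4 they fell in 8 and rose in 1 (mean -0.69, adjusted p = 1.67e-06, adjusted p = 0.0747 with an estimated correlation). Without the arrays set apart 5 and 8 fell and 1 rose with each (means -0.71 and -0.75, adjusted p = 0.00212 and 5.65e-05, adjusted p = 0.435 and 0.199 with an estimated correlation). ER chaperone genes fell in 4 of 20 with compound 3 (6 adjusted over the list alone; mean -0.41, adjusted p = 1.34e-05, adjusted p = 0.388 with an estimated correlation). On the kept array they fell in 8 (mean -0.81, adjusted p = 0.202 with an estimated correlation). With compound 4 they fell in 9 (15 adjusted over the list alone; mean -0.60, adjusted p = 2.91e-10, adjusted p = 0.0747 with an estimated correlation). On its kept arrays they fell in 12 (mean -0.80, adjusted p = 0.0531 with an estimated correlation). Iron regulon genes rose in 4 of 27 with each (5 and 7 adjusted over the list alone; means 0.38 and 0.42, adjusted p = 0.000415 and 0.000146, adjusted p = 0.688 and 0.522 with an estimated correlation). Without the arrays set apart they rose in 9 and 6 (means 0.95 and 0.57, adjusted p = 0.23 and 0.373 with an estimated correlation), but these rest on number 1 arrays (0.947 for compound 3, 0.884 beside 0.252 for compound 4), and number 1 was highest for every compound in 2-copy cells. Compound 3 changed 219 genes up and 374 down (102 and 223 with a dye term, 194 and 238 on the kept array). Compound 4 changed 224 up and 363 down (112 and 240 with a dye term, 312 and 526 on the kept arrays). Without replicate 3 the 593 genes of compound 3 became 202, and without replicate 2 the 587 of compound 4 became 195. In fits to their own 3 arrays they gave 0 and 9.

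Compounds 5 and 6 changed fewer genes in 2-copy cells than the others did (n = 3 each), except in fits to their own arrays, where compounds 3 and 4 changed few too. With compound 5 the glucan synthesis gene KNH1 (YDL049C, 0.73 ± 0.524), RPL36A (YMR194W, 0.55) and the histone acetyltransferase subunit HAT2 (YEL056W, 0.38) rose. Pyruvate decarboxylase PDC5 (YLR134W, -1.34 ± 0.902), adenylosuccinate lyase ADE13 (YLR359W, -0.99), BDF2 (YDL070W, -0.80), the elongation factor YEF3 (YLR249W, -0.63) and HUT1 (YPL244C, -0.59) fell. Heat shock genes fell in 2 of 24 with it (7 adjusted over the list alone; mean -0.43 and lower on 2 of 3 arrays, adjusted p = 3.08e-08, adjusted p = 0.35 with an estimated correlation). Compound 5 changed 7 genes up and 56 down (17 and 49 with a dye term). The total of 63 became 24 without replicate 1, 135 without the arrays set apart and 0 in a fit to its own arrays. Compound 6 gave 0 genes past limma's threshold (71 at unadjusted p under 0.05, 0 with a dye term), but 84 with array scaling and 156 with array weights (129 and 20 for compound 5). Its number 3 array, set apart, had a weight of 6.71 against 0.623 and 1.4 for the others, so that it counted most in the 156. On its 2 kept arrays 1 gene, YGR045C, named after its value was seen, stood at 0.86 (adjusted p = 0.0318). With all arrays the respiratory chain list stood at -0.06, lower on 2 of 3 arrays (adjusted p = 0.0184, adjusted p = 0.973 with an estimated correlation; on the kept arrays -0.06, adjusted p = 0.0685).

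In vector cells (n = 3 each), which asked what a compound does without alpha-synuclein, compounds 1 and 2 raised FIT3 by 1.5 ± 0.398 and 1.75 ± 0.669. Compound 1 also raised the ammonium permease MEP2 (YNL142W, 1.16) and the plasma membrane proton pump PMA1 (YGL008C, 1.00). It lowered ARO10 (YDR380W, -1.59), the lysine synthesis enzyme LYS20 (YDL182W, -1.06) and the arginine synthesis enzyme ARG1 (YOL058W, -1.05). Compound 2 raised YRO2 (YBR054W, 2.50 ± 0.438) and YGP1 (YNL160W, 2.05) and lowered the amino acid exporter AQR1 (YNL065W, -1.90), HMI1 (YOL095C, -1.48) and HXT2 (-1.44). Compound 4 lowered HXT2 (-1.59 ± 0.0333) and LYS20 (-0.84), and compound 5 the splicing helicase PRP16 (YKR086W, -1.18 ± 0.97). Amino acid biosynthesis genes fell in 10 of 55 with compound 1 (15 adjusted over the list alone; mean -0.27, adjusted p = 8.38e-07, adjusted p = 0.45 with an estimated correlation). With compound 2 they fell in 6 (9 adjusted over the list alone; mean -0.17, adjusted p = 0.000875, adjusted p = 0.829 with an estimated correlation). With compound 3 they fell in 3, including ARG1 (-1.14) and ARG3 (YJL088W, -0.81) (10 adjusted over the list alone; mean -0.21, adjusted p = 3.12e-10, adjusted p = 0.0973 with an estimated correlation). With compound 4 LYS20 was the 1 member that fell (6 adjusted over the list alone; mean -0.18, adjusted p = 1.43e-07, adjusted p = 0.316 with an estimated correlation). Iron regulon genes with compound 2 rose in 1 of 27, FIT3 (mean 0.28, adjusted p = 0.0037, adjusted p = 0.829 with an estimated correlation).

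Gene counts in vector cells were 285, 107, 14, 18, 42 and 0 for compounds 1 to 6, of which 54, 43, 7, 6, 5 and 0 rose. Array scaling gave 386, 299, 636, 589, 175 and 290 and array weights 1234, 1810, 1248, 1164, 147 and 171. Compound 6 gave 247 genes at unadjusted p under 0.05 with limma and, without the arrays set apart, 1 past the threshold: the clathrin heavy chain CHC1 (YGL206C, 0.62), chosen after its value was seen. With a dye term the counts were 120, 110, 0, 2 (HXT2 and LYS20), 1 (PRP16) and 0, and compound 3 gave 374 at unadjusted p under 0.05. Without replicate 2 compounds 1 to 4 gave 9, 21, 0 and 6 genes, and without replicate 1 compounds 1 and 6 gave 565 and 11.

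With compound in both strains (n = 3 each), 2-copy cells still had higher PHO84 than vector cells, by 3.28 ± 0.64 with compound 1, 2.89 with compound 2, 4.73 ± 0.441 with compound 5 and 4.27 ± 0.545 with compound 6 (4.22 on the kept array). FIT2 was higher by 4.53 ± 1.66 and 4.17 ± 2.35 with compounds 1 and 2 and the siderophore transporter SIT1 (YEL065W) by 3.02 and 2.80. MF(ALPHA)2 (-2.31 and -1.98), ACO1 (-1.60 and -1.63) and CYC1 (-1.57 and -1.55) were lowest with them. With compound 5 ULI1 (3.94 ± 0.858) and KAR2 (3.40 ± 1.27) followed PHO84, and ACO1 (-1.99), MF(ALPHA)2 (-1.94) and HXT6 (-1.85) were lowest. PIR3 was higher by 3.76 ± 0.262 with compound 3, 3.63 with compound 4 and 3.98 with compound 6 (4.06, 4.17 and 4.14 on the kept array of each). CRG1 (YHR209W, 2.29 and 2.24; kept 2.60 and 2.49) and PHO84 (2.52 and 2.47; kept 2.09 and 1.88, adjusted p = 0.0988 and 0.15) followed with compounds 3 and 4, and SUL1 (3.42, kept 3.47) and UTR2 (YEL040W, -1.77, kept -1.84) with compound 6. The lowest genes with all arrays were HXT9 (YJL219W, -1.79, -1.84 and -1.95 with compounds 3, 4 and 6), KTR6 (YPL053C, -1.53, -1.76 and -1.79) and, with compound 3, DIP2 (YLR129W, -1.61). On the kept arrays none of these was past the threshold (HXT9 -1.26, -1.28 and -1.01, KTR6 -0.35, -0.50 and -0.15, DIP2 -0.55). AGA1 (YNR044W) stood at -1.23 with compound 4 (kept -1.25, adjusted p = 0.000708).

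ER chaperone genes were higher in 2-copy cells in 2 of 20 with compound 1 (4 adjusted over the list alone; mean 0.37, higher on 2 of 3 arrays, adjusted p = 0.00018, adjusted p = 0.194 with an estimated correlation). With compound 2 the 1 member that was higher was YET1 (0.70; list mean 0.22, higher on 2 of 3 arrays, adjusted p = 0.027, adjusted p = 0.521 with an estimated correlation). With compound 5 they were higher in 16 (16 and 1 lower adjusted over the list alone; mean 1.09, adjusted p = 1.18e-11, adjusted p = 0.0199 with an estimated correlation). With compound 6 they were higher in 9 (mean 0.58) and on the kept array in 13 (mean 1.27, adjusted p = 6.52e-10, adjusted p = 0.0719 with an estimated correlation). Iron regulon genes were higher in 21 of 27 with compound 1 (25 adjusted over the list alone; mean 1.32, adjusted p = 6.21e-35, adjusted p = 0.000602 with an estimated correlation). With compound 2 20 were higher (22 adjusted over the list alone; mean 1.21, adjusted p = 4.25e-33, adjusted p = 0.0015 with an estimated correlation). Respiratory chain genes were lower in 19, 12 and 30 of 37 with compounds 1, 2 and 5 and higher in 0, 0 and 1 (means -0.47, -0.41 and -0.61, adjusted p = 0.000602, 0.0028 and 0.0118 with an estimated correlation). Mitochondrial ribosome genes were lower in 21, 14 and 66 of 71 with these (means -0.47, -0.45 and -0.79, adjusted p = 0.0629, 0.0733 and 0.065 with an estimated correlation). With compound 3 they were lower in 16 and higher in 1 (mean -0.35, adjusted p = 1.33e-10, adjusted p = 0.55 with an estimated correlation). On the 1 kept array of each of compounds 3, 4 and 6 their means were -0.93, -0.85 and -0.95, with no replicate to give a spread. Gene totals were 446, 310, 867, 844, 1921 and 2242 for compounds 1 to 6, of which 213, 113, 460, 511, 1052 and 1256 were higher (196, 116, 642, 486, 1652 and 1792 in all with a dye term). Compounds 3, 4 and 6 gave 561, 572 and 1247 on the kept arrays, and compound 2 gave 494 in the fit without the arrays set apart. Without replicate 2 the totals of compounds 1, 2 and 5 became 59, 81 and 726. Without replicate 3 those of compounds 3, 4 and 6 became 292, 262 and 1321.

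The response of 2-copy cells minus that of vector cells asked whether a compound acts differently where alpha-synuclein is made. For compound 1, FIT2 responded by 4.27 in 2-copy and 1.05 in vector cells, a difference of 3.22 (SE 0.927, adjusted p = 0.0123). PRM1 differed by 2.08 and FIT3 by 2.00. ULI1 (-3.35), KAR2 (-3.03, from -3.16 against -0.13) and PIR3 (-2.84) differed the other way. For compound 2, FIT2 (3.00), PRM1 (1.96) and HXT6 (1.91) were higher and ULI1 (-4.09), KAR2 (-3.48) and CPP3 (YDR034W-B, -3.07) lower. ER chaperone genes differed downward in 11 of 20 for compound 1 (14 adjusted over the list alone; mean -0.90, adjusted p = 1.55e-08, adjusted p = 0.202 with an estimated correlation). For compound 2 they did so in 12 (14 adjusted over the list alone; mean -1.10, adjusted p = 2.52e-12, adjusted p = 0.0267 with an estimated correlation). Iron regulon genes differed upward in 9 of 27 for each (10 and 11 adjusted over the list alone; means 0.80 and 0.73, adjusted p = 2.64e-06 and 1.32e-06, adjusted p = 0.246 and 0.184 with an estimated correlation). Mitochondrial ribosome genes did so in 29 and 27 of 71 (49 and 52 adjusted over the list alone; means 0.68 and 0.64, adjusted p = 9.98e-18 and 1.3e-18, adjusted p = 0.246 and 0.184 with an estimated correlation).

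For compound 3, CWP1 (1.27), DSE4 (1.26), SCW11 (1.24, kept 1.74) and, downward, PHO89 (-2.10), SPL2 (-1.97) and SUL1 (-1.75, kept -2.00) differed. On the kept arrays CWP1, DSE4, PHO89 and SPL2 had adjusted p = 0.102, 0.11, 0.15 and 0.157. For compound 4, SCW11 (1.35), CTS1 (0.98), the acyl-CoA synthetase FAA3 (YIL009W, 0.79), SPL2 (-2.13, kept adjusted p = 0.0601), SUL1 (-1.58) and ferrochelatase HEM15 (YOR176W, -1.21, kept adjusted p = 0.0608) differed. Compound 5 gave 4 genes, the spermine synthase SPE4 (YLR146C, 1.14, but -0.11 with adjusted p = 0.914 from the other 2 sides of the loop), KNH1 (0.91), SKI3 (YPR189W, -0.71) and, chosen after its value was seen, PRP16 (1.10). For compound 4, phosphate genes differed downward in 1 of 17, SPL2 (5 adjusted over the list alone; mean -0.68, adjusted p = 0.0619 with an estimated correlation; kept mean -0.74, adjusted p = 0.1 with an estimated correlation). Counts were 895 (392 up, 503 down), 808 (263 up, 545 down), 100 (27 up, 73 down), 23 (6 up, 17 down), 4 and 0 for compounds 1 to 6. Compounds 3, 4 and 6 gave 96, 148 and 0 on the kept arrays (143 for compound 6 at unadjusted p under 0.05 with limma). The other 2 sides of the loop, which use arrays set apart for compounds 3, 4 and 6, gave 1050, 1267, 1448, 1399, 280 and 1511, and array scaling gave 294, 332, 469, 203, 31 and 21. Compound 6 gave 95 and compound 5 gave 571 genes at unadjusted p under 0.05 with limma. The lowest counts without 1 replicate were 493 (without 2), 178 (3), 4 (2), 0 (3) and 0 (2) for compounds 1 to 5. Compound 3 gave 262 without replicate 1, where both its arrays in 2-copy cells were set apart.

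Among the 6 compounds, 853 genes differed in response in 2-copy cells (602 on the kept arrays) and 21 in vector cells (27). In 2-copy cells the lowest p belonged to the ER co-chaperone JEM1 (YJL073W, F = 25.2, adjusted p = 2e-10), which stood at -1.32 ± 0.22 with compound 1, -1.61 with compound 2, -1.20 and -1.15 with compounds 3 and 4 (kept -1.17 and -1.29), -0.49 ± 0.397 with compound 5 and -0.14 on the kept arrays of compound 6. The ER retention receptor ERD2 (YBL040C, F = 20.3), PRM1 (F = 19.4), the biotin transporter VHT1 (YGR065C, F = 18.5) and GPB1 (YOR371C, F = 17.8) followed. In vector cells they were PRS2 (YER099C, F = 13.3), PRP16 (F = 13.1), PMA1 (F = 12.5), LYS20 (F = 11.7) and HXT2 (F = 10.5). HXT2 stood at -0.88, -1.44, -1.45 and -1.59 with compounds 1 to 4 and at 0.21 and 0.12 with compounds 5 and 6. Without replicate 2 the counts became 194 and 0, and without replicate 1 they became 1064 and 50.

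Compounds 1 and 2, which differ in iodine against bromine, gave 0 genes that differed in 2-copy cells with limma. Their median difference in size was 0.101, and the 95% interval of a difference reached a median of 0.396 to each side. Differences are given as the first compound of a pair minus the second. FIT2 differed by -0.10 (-1.95 to 1.75) and KAR2 by 0.59 (-0.65 to 1.82). Arrays were not paired by replicate number, so that these intervals include the spread between numbers. On arrays 1 to 3 KAR2 stood at -4.53, -2.63 and -2.31 with compound 1 and lower, at -4.74, -3.44 and -3.06, with compound 2. FIT2 kept no 1 direction (4.73, 3.84 and 4.23 against 4.33, 4.40 and 4.37). Without such pairing, differences within these intervals were not detectable. Compounds 3 and 4, which differ in where the halogens sit, gave 1 gene, RMD6 (YEL072W, -1.11), chosen after its value was seen (3 on the kept arrays), with PHO89 at -0.11 (-1.13 to 0.92). Compounds 5 and 6, of different ring systems, gave 0, with KAR2 at -0.42 (-1.66 to 0.82) and PHO89 at 0.48 (-0.54 to 1.5). Compounds 1 and 6, which share the larger ring system, differed in 776 genes (599 on the kept arrays). In compound 1 minus 6, FIT2 stood at 4.06 (2.21 to 5.91, adjusted p = 0.00203), KAR2 at -3.14 (-4.37 to -1.90, adjusted p = 0.000364) and ERO1 at -2.42. Compound 5, which shares the dimethyl ring system of compound 3, differed from it in 47 genes (14 on the kept arrays), with PHO89 at -2.71 in compound 3 minus 5 (-3.73 to -1.68, adjusted p = 0.00321), SPL2 at -2.39 and HXT2 at -1.94. Compounds 1 and 3, of different ring systems, differed in 379 genes with all arrays and in 1, YDR029W (-1.43, named after its value was seen), on the kept arrays. Compounds 1 and 5 differed in 159 genes (298 kept), 2 and 5 in 299 (466), 2 and 6 in 876 (684), 3 and 6 in 97 (19), 4 and 5 in 10 (51) and 4 and 6 in 53 (53). The other pairs were 1 and 4 with 33 (14), 2 and 3 with 368 (1, again YDR029W at -1.27) and 2 and 4 with 11 (6). In vector cells pairs gave 0 to 17 genes, with 2 for compounds 1 and 2, PRS2 (-0.96) and the phosphatase MSG5 (YNL053W, -0.98), chosen after their values were seen.

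The alpha-synuclein score condensed 1651 genes higher and 1392 lower in arrays 1 to 3 of 2-copy over vector cells at 4 h. Untreated arrays 4 to 6 scored 0.621 ± 0.075 (n = 3). With compounds 1 and 2 the 2-copy over vector score was 0.223 ± 0.123 and 0.187 ± 0.0838. It was 0.186 ± 0.175 and 0.199 ± 0.186 with compounds 3 and 4 (0.387 and 0.414 on the kept array of each), 0.445 ± 0.155 with compound 5 and 0.307 ± 0.237 with compound 6 (kept 0.580). The difference from untreated was -0.397 and -0.433 for compounds 1 and 2 and -0.176 for compound 5, with exact permutation p = 0.1, 0.1 and 0.2, where 0.1 is the smallest that 20 splits can give (adjusted p = 0.15, 0.15 and 0.2). All 18 arrays with compound differed from the 3 untreated ones by -0.363 (exact permutation p = 0.00301, 1330 splits). Without the arrays set apart, 6 of these 18, the difference was -0.281 (exact permutation p = 0.0154), and with array scaling -0.227 (0.0233). Arrays were taken as independent, and compound and array set (untreated 4 to 6) cannot be told apart. The 6 compounds did not differ among themselves past the threshold (permutation p = 0.393), nor without the arrays set apart (0.115). Without replicate 1 this p was 0.00027, but compounds 3, 4 and 6 then had only arrays set apart. On arrays of 2-copy cells with over without compound, the score was -0.375 ± 0.0724, -0.382 ± 0.0256, -0.108, -0.152, -0.136 ± 0.124 and -0.00479 for compounds 1 to 6 (kept -0.197, -0.198 and -0.0147 for 3, 4 and 6). The same arrays of vector cells gave 0.00471 to 0.0431. In the time course the score of 2-copy over vector cells was 0.0062, 0.226, 0.669 and 0.321 at 0, 2, 4 and 6 h and that of 1-copy cells 0.0561 to 0.0709. The 0.669 includes arrays 1 to 3, which chose the genes. Genes chosen at 4 h favour that time, so that a peak there was not tested.

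**Figure D4:**
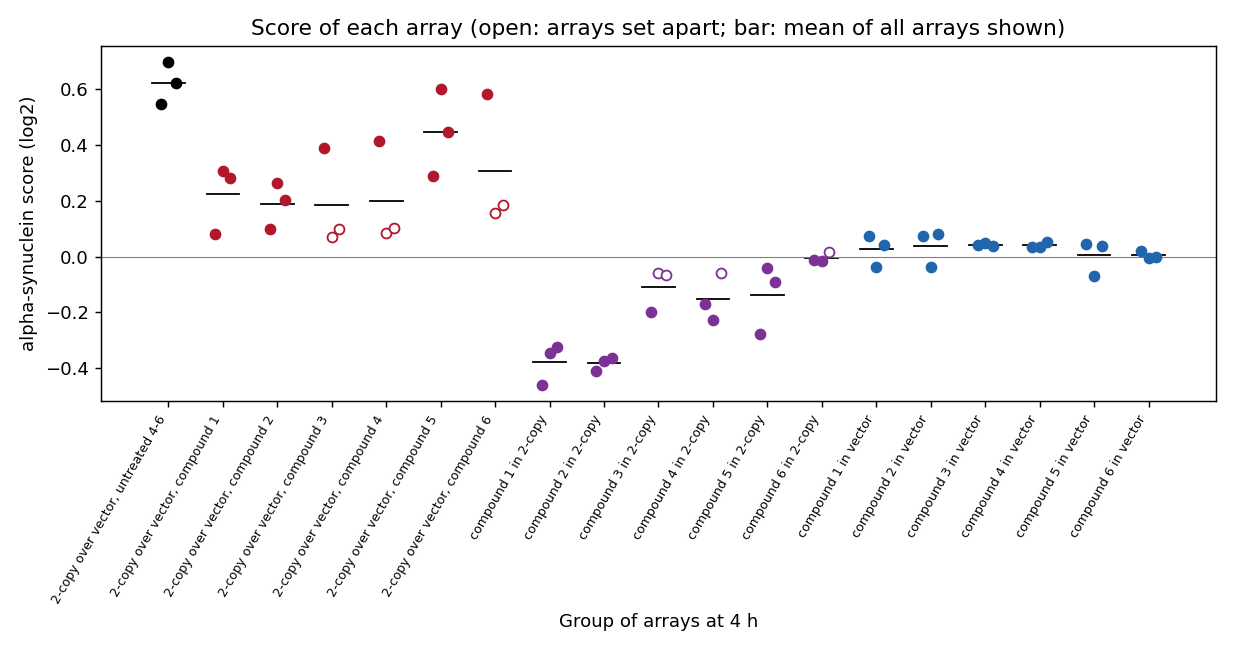
Alpha-synuclein score (y axis, log2) of each array by group at 4 h (x axis); points are arrays, open for the 10 set apart, and bars are means of all arrays shown. Untreated arrays averaged 0.621, those with compounds 1 and 2 averaged 0.223 and 0.187, and those with compound 5 averaged 0.445.

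Of 433 list calls, 407 stayed past the threshold with each array scaled by its spread and 26 did not. With an estimated correlation, 383 of these calls were lost. Counts of genes moved with the model too: 35 of 43 changed by over 1.5 times in a fit to a comparison's own arrays, 34 with arrays scaled and 31 with array weights. The list with a median and mean of different sign among 2-copy over vector lists at 4 h was that of strain markers (median -0.08, mean 0.15, adjusted p = 0.701).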

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

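Tests of the explanations below were chosen after the results were seen, as were the expectations for the counts of other splits, whose rule was fixed beforehand. In outlier checks of 25 values of the 6 arrays of 2-copy over vector at 4 h, 1 lay apart, and chance gives about 1 in 20. On array 1 AIM33 stood at -2.42 and on the other 5 between -1.76 and -1.70, so that its gap to the nearest was 0.92 of the whole range.

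The first pattern weighed is that 10 arrays of compounds 3, 4 and 6 were out of step with the rest. The 6 among them that set 2-copy against vector cells correlated with each other across genes at 0.673 to 0.897 and with the number 1 arrays of the same compounds at 0.214 at most, while those 3 correlated with each other at 0.849 to 0.943. That low value argues against a response to the compounds, and THI5, THI11, THI12 and THI13, near-identical genes, spread by 1.59 on these arrays against 0.0679 on the number 1 arrays, which argues against RNA of another culture under the wrong label. Probe rows assigned to other genes remain a candidate explanation: ribosomal protein genes spread 0.992 times as widely as all genes there, as a random set would, against 0.708 on the number 1 arrays. Of 220 genes beyond 1.2 in size on the number 1 arrays, 28 lay within 0.5 of that value on the 6 arrays (12.7%, against 2.47% by chance), so that how many rows would be affected stays open.

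A further pattern is the lower alpha-synuclein score with compounds 1 and 2 (0.223 and 0.187 against 0.621 untreated). As the whole cause, smaller log ratios on those arrays are argued against by the arrays of 2-copy cells with over without compound, which scored -0.322 at most (lowest -0.458), against -0.0388 to 0.0794 in vector cells. With array scaling the score was 0.557 untreated against 0.369 (SD 0.176) and 0.319 (SD 0.114), so that the differences shrank to -0.188 and -0.238 and a part played by the spread of the arrays stays open. A lower response in cells with the compound remains a hypothesis. The score predicted from the other arrays of the loop differed from the direct one by 0.0130 at most, within the SD of 0.0838. This match would follow from any cause that lowers the score in the cells, so that it cannot tell such causes apart. A weaker galactose promoter stays open: GAL1, GAL7 and GAL10 averaged -0.0558 over the 6 arrays of 2-copy cells with these compounds (SD 0.204), but how far they would need to fall is not known and alpha-synuclein itself has no probe.

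The last pattern is that the iron regulon was higher with compounds 1 and 2 in 2-copy cells (mean 1.01, SD 0.251 over 6 arrays). A dye effect is argued against by a mean of 1.08 with a dye term. Arrays of 1 replicate number are argued against by the lowest of the 6 arrays, 0.827, although number 1 arrays were highest for every compound in 2-copy cells. As the whole cause, a response that needs no alpha-synuclein is argued against by the highest vector array, 0.410 (vector mean 0.240, SD 0.15). An exact permutation gave p = 0.00216 (924 splits), but it treated arrays of both compounds as independent. Same-numbered arrays of 2-copy cells were close (1.35, 0.837 and 0.827 with compound 1, 1.31, 0.855 and 0.862 with compound 2), so that this p may be too small. FIT3 rose in vector cells too (1.5 and 1.75), and the list test of the difference in response had adjusted p = 0.246 and 0.184 with an estimated correlation. That the compounds raise iron uptake genes more with alpha-synuclein is therefore a hypothesis, found and tested on the same arrays.

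By tests of the difference between times, the 2-copy over vector ratio had changed from 0 h in 300 genes at 2 h (60 without replicate 3), 2443 at 4 h and 1482 at 6 h (864 without replicate 3). At 4 h, 1 of 84 splits of the arrays gave as many genes, the real one (highest other 1101), a share under 0.05 that argues against chance. The split with 1101 genes set 4 h arrays 4 to 6 against all the others, which points to a structure within the 4 h arrays. At 2 h and 6 h the 10 splits are too few for a share under 0.05 (real 300 and 1482, highest other 51 and 188, 1 split each as large). Genes named by the rule of the methods at 2 h were PHO84 3.56, INO1 2.45, SIP18 2.02, CTR1 -2.37, HXK1 -2.23 and MAM33 -1.91. At 4 h they were HSP26 5.80, PHO84 5.00, ULI1 4.80, COX17 -3.26, MAM33 -3.09 and HXT6 -2.98, and at 6 h ULI1 4.60, PUT1 3.74, NCW2 3.53, MF(ALPHA)2 -3.03, HXT6 -2.92 and MF(ALPHA)1 -2.71.

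By tests of the difference between strains, the response of 2-copy minus that of vector cells differed in 895, 808, 100, 23 and 4 genes for compounds 1 to 5. Leaving out 1 replicate lowered these to 493, 178, 4, 0 and 0. Without replicate 1 compound 3 had 262, from 2-copy arrays both set apart. On the kept arrays compound 3 had 96 and compound 4 had 148. For each compound the 10 splits are too few for a share under 0.05: the highest other counts were 609, 203, 1, 0, 65 and 1 for compounds 1 to 6, against 0 real genes for compound 6 (limma, 95 at unadjusted p under 0.05), and 1, 1, 1, 1, 5 and 10 splits gave as many. For compound 5 the split with 65 genes, several times the real count, set 2-copy arrays 1 and 2 with vector array 2 against the rest, which points to a structure of the samples. The same split was the highest other for compounds 1 and 2 (609 and 203), so that it bears on their counts too. For compound 1 the differing genes included FIT2 3.22, PRM1 2.08, FIT3 2.00, ULI1 -3.35, KAR2 -3.03 and PIR3 -2.84, and for compound 2 FIT2 3.00, PRM1 1.96, HXT6 1.91, ULI1 -4.09, KAR2 -3.48 and CPP3 -3.07. For compound 3 they included CWP1 1.27, DSE4 1.26, SCW11 1.24, PHO89 -2.10, SPL2 -1.97 and SUL1 -1.75, for compound 4 SCW11 1.35, CTS1 0.98, FAA3 0.79, SPL2 -2.13, SUL1 -1.58 and HEM15 -1.21, and for compound 5 SPE4 1.14 (-0.11, adjusted p = 0.914, from the other 2 sides of the loop), KNH1 0.91 and SKI3 -0.71.

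By F tests among the 6 compounds, 853 genes differed in 2-copy cells (194 without replicate 2, 602 on the kept arrays) and 21 in vector cells (0 without replicate 2, 50 without replicate 1). In 2-copy cells 4 of 100 splits gave as many (highest other 1107). That share lies too close to 0.05 for 100 splits to exclude chance clearly, and some splits gave more genes than the real one. Over the 15 pairs, 5 of 100 gave as many calls as the real 3109 (highest other 4878), so that chance cannot be excluded for those. These splits included the 4 arrays with compound in 2-copy cells that were set apart. In vector cells 21 of 100 splits gave as many genes as the real 21 (highest other 450), and 36 of 100 as many pair calls as the real 69 (highest other 3258). Chance cannot be excluded there, and splits with many times the real count point to a structure of the samples. The genes of lowest p were JEM1 (F = 25.2), ERD2 (20.3), PRM1 (19.4), VHT1 (18.5) and GPB1 (17.8) in 2-copy cells and PRS2 (13.3), PRP16 (13.1), PMA1 (12.5), LYS20 (11.7) and HXT2 (10.5) in vector cells.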

How the results depend on the processing

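Leaving out the 10 arrays set apart was chosen after seeing the data, and the other settings were planned. Directions held in most settings, while calls and counts depended on how the spread between arrays was estimated, with 3 arrays in most groups. The block for replicate number, run for differences between groups alone, kept their counts within 1.5 times. Tests of the signature kept their side of the threshold in every setting but 1. For single compounds that was fixed in advance, as 20 splits give no p below 0.1. Of 240 named gene results, 99 lost their call in a fit to their own arrays, 5 with array scaling, 5 with array weights, 17 without the arrays set apart, and 23, 53 and 41 without replicates 1, 2 and 3. All these kept their direction. Of 433 list calls, 383 were lost with an estimated correlation, 26 with array scaling, 27 of 321 with a dye term, 13 without the arrays set apart, and 110, 54 and 53 without replicates 1, 2 and 3. A further 2 reversed with a dye term, and a further 7, 2 and 2 without replicates 1, 2 and 3. Where leaving out a replicate left 1 array, it was assumed to vary like the other groups. Another background correction, a filter on signal and a block for slide were not run, since intensities and slides were not analysed here. A fit to probes without missing values moves nothing, as 0 were missing. Pairing the signature test by replicate number was not run, as untreated arrays 4 to 6 share no number with the compound arrays. Without intensities, signal over background sets no known limit. For every value below, the cause was not tested, except that leaving out a replicate or fitting 3 arrays alone uses fewer arrays.

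With a dye term, 2-copy over vector had 328 genes at 0 h and 408 at 2 h, 1-copy over vector had 3, 1, 2 and 4 at the 4 times and 1-copy over 2-copy had 24 at 0 h and 204 at 2 h. Compounds 3 and 4 in 2-copy cells had 325 and 352, and compounds 1, 3, 4 and 5 in vector cells had 120, 0, 2 and 1. With compounds 1, 2 and 4 in both strains, 2-copy over vector had 196, 116 and 486. Lists past the threshold in vector cells became 33. In vector cells the ER chaperone list with compound 4 reversed to 0.028 (adjusted p = 0.703) and the ribosomal protein list with compound 6 to -0.17 (adjusted p = 0.00232).

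In a fit to its own arrays, 2-copy over vector had 0 genes at 0 h and 923 at 6 h. One-copy over vector had 2, 0, 134 and 5, and 1-copy over 2-copy had 0 at 0 h, 1339 at 2 h and 1160 at 6 h. Changes from 0 h had 11 at 2 h and 454 at 6 h. Compounds 1 to 5 had 623, 1277, 0, 9 and 0 in 2-copy cells and 0, 0, 360, 47 and 0 in vector cells. Both strains compared with compounds 1 to 6 had 80, 0, 5, 0, 573 and 3. Differences in response had 2, 514 and 17 for compounds 1 to 3 and 0 for compound 5. The F tests gave 218 and 5 genes in 2-copy and vector cells, and the 15 pairs 1000 and 34 calls.

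With array weights, 2-copy over vector had 438 genes at 0 h and 1497 at 2 h, 1-copy over vector had 1789, 1177, 1339 and 671, and 1-copy over 2-copy had 392 at 0 h and 1962 at 2 h. The change from 0 h had 871 at 6 h. Compounds 4, 5 and 6 had 910, 20 and 156 in 2-copy cells, and compounds 1 to 6 had 1234, 1810, 1248, 1164, 147 and 171 in vector cells. The 2-copy over vector comparisons with compounds 1, 2 and 4 had 1976, 552 and 1469. Differences in response had 1349, 1733, 668, 515, 65 and 73. The F tests gave 1441 and 1109 genes and the pairs 7181 and 4261 calls in 2-copy and vector cells.

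With array scaling, 2-copy over vector had 2331 genes at 4 h and 890 at 6 h, 1-copy over vector had 501, 683, 634 and 728, and 1-copy over 2-copy had 707, 1422 and 974 at 0, 4 and 6 h. Changes from 0 h had 1434 at 4 h and 420 at 6 h. Compounds 1, 2, 5 and 6 had 897, 1066, 129 and 84 in 2-copy cells, and compounds 2 to 6 had 299, 636, 589, 175 and 290 in vector cells. The 2-copy over vector comparisons with compounds 1, 2, 5 and 6 had 762, 707, 957 and 1148. Differences in response had 294, 332, 469, 203, 31 and 21. The F tests gave 399 and 298 genes and the pairs 1450 and 809 calls. Lists past the threshold in vector cells became 28.

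Without the arrays set apart, compounds 5 and 6 had 135 and 1 genes in 2-copy cells, compounds 3 and 6 had 22 and 1 in vector cells, the 2-copy over vector comparisons with compounds 2, 3 and 6 had 494, 561 and 1247, and the difference in response to compound 4 had 148. Computed from the other 2 sides of each loop of arrays, differences in response had 1267, 1448, 1399, 280 and 1511 genes for compounds 2 to 6, and SPE4 reversed to -0.11 for compound 5 (adjusted p = 0.914, against 1.14). With an estimated correlation, the lists past the threshold became 6 of 56 for 2-copy over vector, 3 of 25 for 1-copy over vector, 5 of 51 for 1-copy over 2-copy and 11 of 51 for changes from 0 h. For compounds they became 2 of 77 in 2-copy cells, 0 of 16 in vector cells, 19 of 96 for 2-copy over vector with compound and 4 of 61 for differences in response.

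Leaving out 1 replicate number in turn gave these ranges, with the number left out in brackets. For 2-copy over vector they were 301 (3) to 715 (2) genes at 0 h and 165 (3) to 585 (1) at 2 h. For 1-copy over vector they were 30 (2) to 73 (1), 53 (3) to 267 (2), 4 (3) to 10 (2) and 11 (2) to 35 (3). For 1-copy over 2-copy they were 15 (3) to 293 (1) at 0 h and 234 (3) to 364 (1) at 2 h, and for changes from 0 h 60 (3) to 248 (2) at 2 h and 864 (3) to 1163 (1) at 6 h. In 2-copy cells compounds 3 to 6 gave 202 (3) to 683 (1), 195 (2) to 513 (3), 24 (1) to 84 (2) and 0 (1) to 1 (2). In vector cells compounds 1 to 4 gave 9 (2) to 565 (1), 21 (2) to 86 (1), 0 (2) to 8 (1) and 6 (2) to 15 (1), and compound 6 gave 0 (2) to 11 (1). The 2-copy over vector comparisons with compounds 1 to 6 gave 59 (2) to 707 (1), 81 (2) to 575 (1), 292 (3) to 1033 (1), 262 (3) to 1002 (1), 726 (2) to 2191 (1) and 1321 (3) to 2294 (1). Differences in response gave 493 (2) to 610 (1), 178 (3) to 616 (1), 4 (2) to 262 (1), 0 (3) to 6 (1), 0 (2) to 6 (1) and 0 (1) to 1 (2). The F tests gave 194 (2) to 1064 (1) in 2-copy and 0 (2) to 50 (1) in vector cells, and the pairs 692 (2) to 4432 (1) and 8 (2) to 266 (1) calls. Lists past the threshold ranged over 14 (1) to 25 (2) for 1-copy over vector and 17 (3) to 25 (2) in vector cells with compound. The permutation p among compounds ranged over 0.00027 (1) to 0.736 (3). Without replicate 1, compound 3 in 2-copy cells, the 2-copy side of its difference in response and 2-copy over vector with compounds 3, 4 and 6 rest on arrays set apart alone, and the p of 0.00027 sets these against compounds 1, 2 and 5.

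List means whose camera direction turned when 1 replicate was left out ranged as follows. Ribosomal proteins in 1-copy over vector at 0 h gave -0.132 (1) to 0.361 (3), and ribosome biogenesis -0.0134 (1) to 0.176 (3) there at 4 h and -0.0911 (3) to 0.268 (2) in 1-copy over 2-copy at 0 h. Mitochondrial chaperones in 1-copy over 2-copy at 0 h gave -0.372 (2) to 0.0257 (3). Glycolysis with compound 5 in 2-copy cells gave -0.419 (2) to 0.0515 (1). The proteasome list gave -0.207 (3) to 0.0345 (2) with compound 2 in vector cells and -0.00693 (2) to 0.217 (1) in 2-copy over vector with compound 2. General stress genes gave 0.0379 (1) to 0.647 (2) in 2-copy over vector with compound 4 and -1.18 (2) to 0.128 (1) for the difference in response to compound 1. For differences in response, iron regulon genes gave -0.0456 (1) to 0.511 (3) with compound 4 and ribosomal proteins -0.062 (1) to 0.297 (2) with compound 5.

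With replicate number as a block, changes from 0 h had 312, 2000 and 1496 genes, differences in response had 931, 828, 115, 27, 4 and 0, and the F tests gave 850 and 22. Pairs gave 3231 and 73 calls, list calls numbered 51 for changes from 0 h and 61 for differences in response, and the permutation p among compounds was 0.454. The block changed no call of these results or of a named gene, and 1 single list became weaker.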

Other observations

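No test was chosen here after a result was seen, but the genes named were, to show the size of changes in the fixed gene lists not described above. In 2-copy over vector cells at 4 h (n = 6), nutrient and stress lists rose on 6 of 6 arrays. Of sulfur and methionine genes 19 of 29 rose and 3 fell (mean 0.87, adjusted p = 9.08e-06, 0.133 with an estimated correlation; MET14 2.07, SUL2 1.92). Of phosphate genes 13 of 17 rose and 1 fell (mean 0.99, adjusted p = 0.000332, 0.139; PHM8 2.37, GIT1 2.28). Zinc genes rose in 7 of 13 and fell in 2 (mean 0.47, adjusted p = 0.022, 0.139). General stress and reserve carbohydrate genes rose in 20 of 28 and fell in 2 (21 and 2 adjusted over the list alone; mean 1.18, adjusted p = 6.11e-05, 0.309; GRE1 3.16). Genes of ER-associated degradation rose in 12 of 16 (13 adjusted over the list alone; mean 0.55, adjusted p = 0.000326, 0.0985; DFM1 1.44), and glycolysis rose in 14 of 19 and fell in 3 (mean 0.50, adjusted p = 0.00492, 0.309; PDC1 1.75).

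Lists of growth and mating fell in the same comparison. Mitochondrial chaperones and proteases fell in 9 of 14 and rose in 1 (mean -0.45, 6 of 6 arrays, adjusted p = 0.00293, 0.139 with an estimated correlation; MGE1 -1.28, HSP60 -0.91). Histone and S phase genes fell in 14 of 24 and rose in 2 (mean -0.28, 6 of 6 arrays, adjusted p = 0.00822, 0.201; HTB2 -0.86), and ribosome biogenesis genes fell in 28 of 74 (23 adjusted over the list alone; mean -0.23, 5 of 6 arrays, adjusted p = 0.00162, 0.589). Mating type alpha genes fell in 4 of 4 (mean -0.91, 6 of 6 arrays, adjusted p = 0.0199, 0.155; MF(ALPHA)1 -1.35) and haploid genes in 7 of 13, with 1 risen (mean -0.38, 6 of 6 arrays, adjusted p = 0.0317, 0.139; HO -1.96, SST2 -0.94, FAR1 -0.82). In 2-copy cells the haploid list was higher with compound 1 (3 of 13 risen, mean 0.42, 3 of 3 arrays, adjusted p = 0.0434, 0.247) and compound 2 (5 of 13 risen, mean 0.52, 3 of 3 arrays, adjusted p = 0.0056, 0.135). The haploid list was not past the threshold at 4 h without replicate 1 (adjusted p = 0.0647), nor with compound 1 without replicate 2 (0.0825) or replicate 3 (0.0873).

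Lists not past the threshold at 4 h were iron (9 of 27 risen, 3 fallen, mean 0.34, adjusted p = 0.184; TIS11 2.69), ergosterol (9 of 26 risen, 3 fallen, mean 0.17, 0.306), drug efflux (9 of 20 risen, 3 fallen, mean 0.34, 0.184) and galactose genes (5 of 10 fallen, mean -0.29, 0.116; GAL2 -1.03). Amino acid biosynthesis (15 of 55 risen, 14 fallen, mean 0.03, 0.552), phospholipid and inositol genes (4 of 19 risen, 7 fallen, mean -0.08, 0.281) and mating type a genes (3 of 8 fallen, mean -0.17, 0.188) were not past it either.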
